A study of Mus musculus with 8 samples.

How the data were processed

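Chromatin from MEFs was immunoprecipitated with an antibody against Foxk1 (3 libraries) or with IgG (3 libraries), or kept as input (2 libraries), and sequenced. Groups were taken from the antibody label, and for input from the sample titles. Per the submitters' processing notes, reads were aligned to mm9 with Bowtie, whose version is not given in the sources used here. The track line names the deposited peaks as Foxk1 against input on mm9. The peak caller, its settings, and whether the Foxk1 or input libraries were pooled before calling are not given in the sources used here.

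The authors deposited a narrowPeak table with a signal value (a score with no stated scale, not named as a fold) and a q-value for each peak. The deposited q-values are on a linear scale, from 0.00014 to 0.00995, rather than as negative logarithms. Name, strand and p-value fields hold fillers. Because the only table holds 1 comparison, no value per library, per replicate or for IgG was analysed, depth is unknown, and no replicate spread or interval for the counting error of reads could be computed.

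Coordinates are given 1-based on mm9. A genome sequence and gene annotation of mm9 were not used here, and a gene table of a different assembly was not set against these coordinates. The analyses planned before the data were examined that need them were therefore not run: the position of peaks relative to genes, promoter binding of gene groups (glycolysis, hypoxia, autophagy, ribosome and other lists), motifs and sequence words at summits, and signal by location. For the same reason no gene is named for any peak. The planned comparisons of peak number, density by chromosome and spacing were run. The rule for naming items, set at the same time, was the 10 peaks of highest signal value, by coordinates. The planned ranking by q-value came first, but its 3564 ties left the order to the signal value.

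Density was the number of peaks per Mb on chromosomes 1 to 19 and X, with the highest peak end on each chromosome as its length. It was tested by a chi-square statistic against 10000 multinomial draws. As tests added after seeing the data, full 5 Mb windows were permuted between chromosomes 10000 times, for all chromosomes and for each against the overall mean, and 95% intervals came from 2000 resamplings of the windows of a chromosome, for all peaks and for those with a signal value of at least 50. Median signal values were compared by permuting 5 Mb windows with their peaks 1000 times. Exact Poisson intervals of peak counts, the choice made beforehand, were computed as well (20.7 to 23.1 peaks per Mb for chromosome 19), but they ignore the clumping of peaks and are too narrow. Benjamini-Hochberg adjustment covered the 20 chromosomes of each test. Spacing was the median distance between neighbouring summits, compared with 1000 shuffles of positions between the first and last summit of each chromosome, or within 1 Mb windows, and 200 shuffles gave the counts by distance class. Signal values of neighbouring peaks were compared by Spearman's correlation with values permuted within chromosomes 1000 times. Tests of single chromosomes, of spacing and of correlation were two-sided.

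Alternatives were the peaks at or above the median signal value, a q-value of at most 0.001, merging of peaks less than 100 bp apart or of summits less than 2000 bp apart, other measures of chromosome length, and counting 100 kb windows with at least 1 peak. Procedures were tested on simulated lists of 28932 peaks. With uniform positions the chi-square test gave p under 0.05 in a share of 0.05 of 400 lists, and the ratio of observed to shuffled spacing was 1.01. With chromosome 7 simulated at 0.5 of the density of the others and positions otherwise uniform, the window test called 1 chromosome. The density ratio of chromosome 7 came out at 0.54. The window test was not tried on clumped positions. With regional density as the only structure, the spacing ratio was 0.60 within chromosomes and 1.00 within 1 Mb windows. That density was drawn for the same 1 Mb windows, so the 1.00 follows from the construction. It does not show how the shuffle treats density that changes inside a window. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.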

Results

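Foxk1 is a forkhead box transcription factor, a protein that binds DNA through a winged-helix domain. Its binding was mapped by chromatin immunoprecipitation followed by sequencing in untreated mouse embryonic fibroblasts (MEFs), the connective-tissue cells cultured from embryos. The series held 8 libraries, of which 3 were immunoprecipitated with an antibody against Foxk1, 3 with control IgG and 2 were input, chromatin taken without any antibody. The values analysed here were a single list of 28933 peaks, named in its track line as Foxk1 against input on the mm9 assembly. This list gave 1 value per peak and none per library, so that no result below carries a replicate error. Read depth per library is not given in the sources used here, and no value for the IgG libraries was used. Every test below takes peaks or stretches of the genome as its units, and its p-value measures the spread along the genome, not between cultures.

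The first question was where the Foxk1 immunoprecipitation was enriched over input and how strongly. Without values for IgG, enrichment not specific to the Foxk1 antibody cannot be told apart, here or in the results below. Peaks lay on all 19 autosomes and on X, and 1 peak lay on Y. The highest peak was on chromosome 12, from 32635236 to 32635695, with a signal value of 391. Next came chromosome 19 from 46835652 to 46836111, with a signal value of 319, and chromosome 17 from 74888543 to 74889002, with 299.9. Chromosome 11 held the next pair, from 120092739 to 120093198 with a signal value of 296 and from 68908138 to 68908597 with 276. The remaining members of the 10 highest peaks had signal values between 263 and 269. They started at 151384332 on chromosome 4, 98711554 on chromosome 15, 38869992 and 26443881 on chromosome 7, and 7416215 on chromosome 19. Of these 10 peaks, 6 had another peak within 10 kb. Within only 5 kb, 39.6% of all peaks and 45.3% of the 10% with the highest signal values had one. The 6 of 10 are thus not shown to be unusual. The peak starting at 120092739 on chromosome 11 had a companion with a signal value of 142 at a distance of 1164 bp, whereas 4 of the 10 stood alone in their 10 kb.

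Most peaks were far weaker than these. The median signal value was 17.8, the 25th and 75th percentiles were 13.5 and 27.6, and the lowest value listed was 11.32. A signal value of at least 50 was reached by 2305 peaks, or 7.97% of the list, 426 reached 100 and 58 reached 200. All peaks had a q-value under 0.01, and 3564 of them (12.3%) shared the lowest q-value of 0.00014, which was given to signal values of at least 40.4. The signal and q-values are those the authors gave for each peak. All peaks were 460 bp wide with the summit in the centre, and together they covered 13.2 Mb.

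A second comparison asked whether detected peaks were spread evenly over the chromosomes. They were not: chromosome 19 carried 21.9 peaks per Mb (95% interval 18.6 to 25.5, from resampling 5 Mb windows) and X carried 3.42 (2.35 to 4.41), against 10.98 over all chromosomes compared. Density was also high on chromosome 11, with 17.3 peaks per Mb (13.9 to 20.2), on chromosome 15, with 16.7 (12.1 to 20.04), and on chromosome 10, with 15.2 (12.5 to 18.0). Among autosomes the sparsest were chromosome 12, with 5.98 peaks per Mb (4.45 to 7.50), and chromosome 7, with 6.19 (4.58 to 7.65). Chromosome 7 thus held 944 peaks, fewer than the 1342 of chromosome 19, although its highest peak coordinate was 153 Mb and that of chromosome 19 was 61.3 Mb. These lengths include any sequence to which reads cannot be assigned. The 13 other chromosomes lay between 8.47 peaks per Mb on chromosome 4 and 13.9 on chromosome 6.

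**Figure D1:**
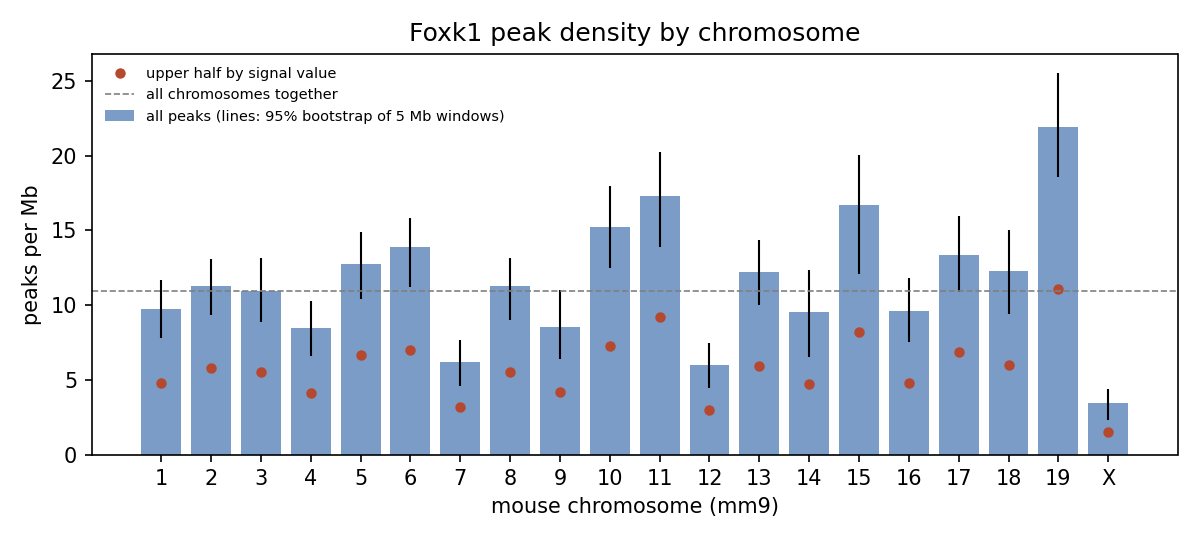
Peaks per Mb (vertical axis) on mouse chromosomes 1 to 19 and X, with length taken as the highest peak coordinate. Bars show all peaks with vertical lines for the 95% interval from resampling 5 Mb windows, points show peaks at or above the median signal value, and the dashed line marks 10.98 peaks per Mb over all chromosomes; chromosome 19 stands highest and X, 12 and 7 lowest in both sets.

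Peak numbers departed from proportionality to chromosome length (chi-square 3553 with 19 degrees of freedom, p = 0.0001 from 10000 multinomial draws, the smallest they can give). Peaks are clumped along chromosomes, and the variance of counts in 518 windows of 5 Mb was 23.3 times their mean, so that this test overstates its evidence. Permuting the windows between chromosomes, which keeps clumps within a window together, also gave p = 0.0001, the smallest that 10000 permutations can give. Structure longer than 5 Mb, such as the stretch of 12.1 Mb without peaks on X, is broken up by this step. Permutation p-values and intervals from 5 Mb windows, here and for signal values, may therefore overstate the evidence. After Benjamini-Hochberg adjustment over 20 chromosomes in this permutation test, 7 chromosomes differed from the mean. Chromosomes 19, 11, 15 and 10 were higher (adjusted permutation p = 0.0005, 0.0005, 0.0037 and 0.0054), and X, 7 and 12 were lower (0.0005, 0.0005 and 0.0028). The ratio of the densest to the sparsest chromosome was 6.41, and it was 3.66 without X, where chromosome 12 is the sparsest. With X left out, chromosome 4 also fell below the mean (adjusted permutation p = 0.039, against 0.104 with X), and the calls for chromosomes 7, 10, 11, 12, 15 and 19 held.

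Peaks with a signal value of at least 50, a limit chosen after seeing the data, were spread less evenly over the chromosomes than all peaks. They numbered 2.22 per Mb on chromosome 19 (95% interval 1.72 to 2.77) and 0.132 on X (0.055 to 0.206), a ratio of 16.8 against 6.41 for all peaks. That ratio rests on 22 such peaks on X. For peaks at or above the median signal value, the alternative set beforehand, the ratio was 7.50, much closer to that of all peaks. Without X, the ratio of chromosome 19 to chromosome 12 was 6.90 for peaks with a signal value of at least 50 (39 on chromosome 12) and 3.66 for all. Median signal values ranged from 16.4 on X to 18.7 on chromosome 11, but they are medians of a list that ends at a signal value of 11.32, and so are a weak measure of differences in strength. Only X passed the test of its median against all other chromosomes: its median minus the 17.9 of the others was -1.43 (adjusted permutation p = 0.02 over 20 chromosomes, 5 Mb windows permuted). Chromosome 11 had an unadjusted p of 0.022 in this permutation test and an adjusted one of 0.22. Among the 14467 peaks at or above the median signal value, the difference in median from all other chromosomes was -2.56 for chromosome 7 and -2.78 for chromosome 12 (both adjusted permutation p = 0.01), and 1.83 and 1.95 for chromosomes 5 and 17 (adjusted permutation p = 0.02 and 0.045). X did not pass in that set, with a difference of -1.28 (adjusted permutation p = 0.25).

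**Figure D2:**
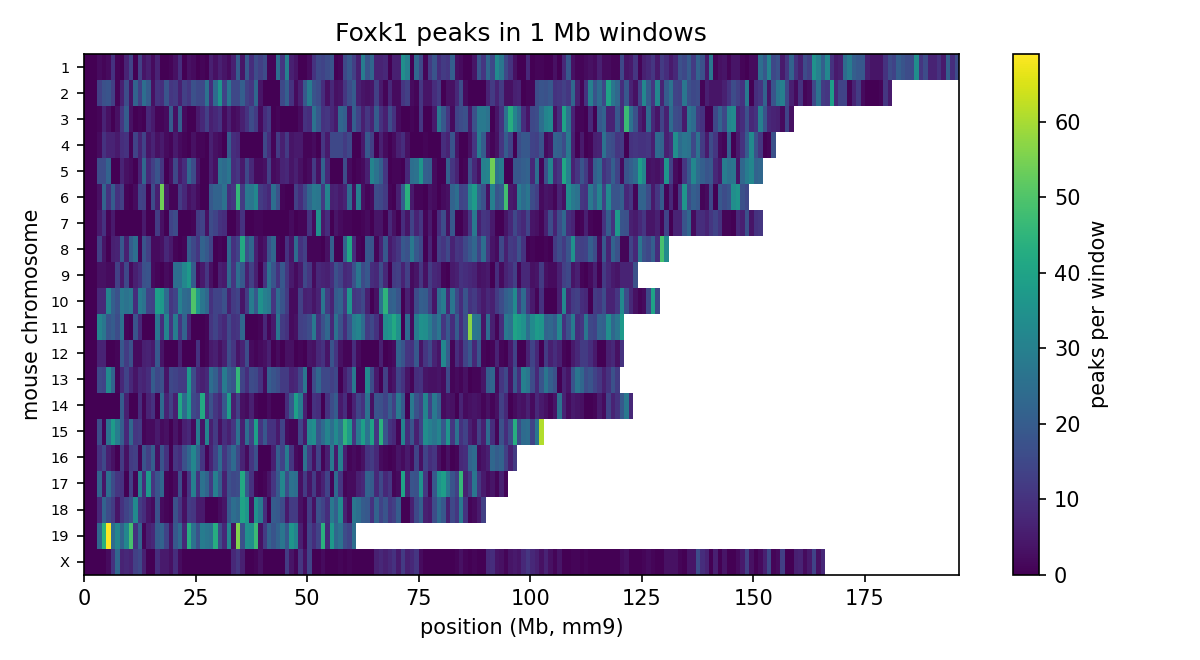
Number of peaks (colour) in successive 1 Mb windows along chromosomes 1 to 19 and X of mm9; the horizontal axis is position in Mb and white lies beyond the last full window. The fullest window, with 69 peaks, lies on chromosome 19 and starts at 5000001, and chromosomes 7 and X show long stretches with few peaks or none.

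A further comparison asked whether peaks gathered in clusters. Neighbouring summits were a median of 24.8 kb apart, against 56.5 kb for positions shuffled within chromosomes, a ratio of 0.44 (two-sided permutation p = 0.002 from shuffled positions, the smallest that 1000 shuffles can give). As a ratio, the excess among distances under 1 Mb was largest at 500 to 1000 bp (8.47 times), where 1551 pairs of neighbouring peaks were found and positions shuffled within chromosomes gave a mean of 183. Pairs at 1000 to 2000 bp numbered 1587 against 362, and pairs at 2000 to 5000 bp numbered 2582 against 1050. Of all peaks, 25.8% had another summit within 2000 bp. The closest summits were 195 bp apart, and 760 pairs of neighbouring peaks overlapped. Long empty intervals were in excess too, with 340 intervals of over 1 Mb against a mean of 20.45 in positions shuffled within chromosomes, which did not leave out stretches where reads cannot be placed. Shuffling within 1 Mb windows, which keeps regional differences in peak number, gave smaller excesses: 5.48 times at 500 to 1000 bp, 2.88 at 1000 to 2000 bp, 1.64 at 2000 to 5000 bp and 1.38 over 1 Mb.

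**Figure D3:**
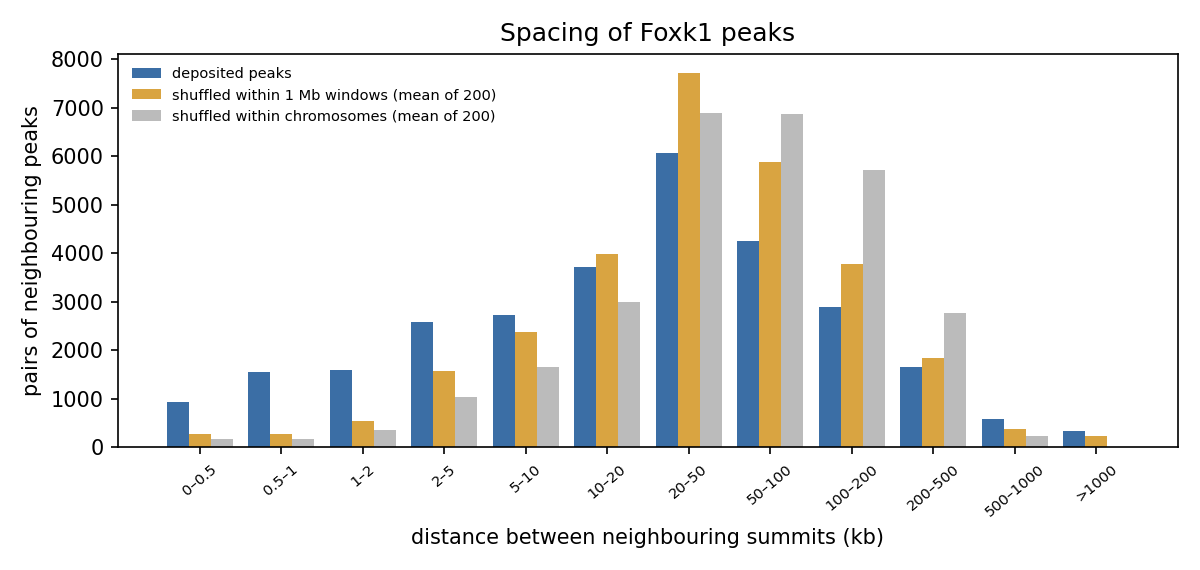
Number of pairs of neighbouring peaks (vertical axis) by the distance between their summits in kb (horizontal axis, classes of unequal width), for the deposited peaks and for the mean of 200 shuffles within 1 Mb windows or within chromosomes. Deposited peaks exceed both shuffles in every class under 10 kb and over 500 kb.

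The clustering held for peaks at or above the median signal value and for merged ones. The former gave a ratio of observed to shuffled spacing of 0.44, and merging summits closer than 2000 bp into 24855 regions gave 0.51 (both permutation p = 0.002). When positions were shuffled within 1 Mb windows, the ratio was 0.64 (permutation p = 0.002).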

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

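Alternatives with a q-value limit or a signal limit of 50, a 2000 bp merge, a different length measure, windows or permutation unit, and all tests of signal values, were chosen after seeing the data. The number of peaks moved from 28933 to 14467 at or above the median signal value and to 14844 at a q-value of at most 0.001, as both keep a part of the list, and by less than 1.5 times with either merge (27748 and 24855 regions). The ratio of chromosome 19 to X, or to chromosome 12 where X was left out, lay between 3.28 (100 kb windows with a peak) and 16.8 (signal values of at least 50). Dividing the densest chromosome by the sparsest gives more than 1 by construction. All alternatives run had p under 0.05. Those with 5 Mb windows permuted allow for clumping within a window. The others took p from multinomial draws, which ignore clumping and overstate the evidence. The ratio of observed to shuffled spacing stayed below 1 and past the threshold, between 0.44 and 0.73, the highest with the 2000 bp merge and 1 Mb windows together. The number of chromosomes whose median signal differed rose from 1 to 4 among peaks at or above the median signal value. A factor per chromosome is set against these medians in the next section, which does not settle the cause. A limit of 5 on the negative log10 q-value left no peak, since the highest was 3.85. Alternatives set beforehand on non-N length, promoters, gene lists, motifs, location classes and sequence words were not run, as their main results were not. No paired analysis was possible because the peak list holds no value per replicate, and leaving out a replicate was not possible for the same reason. Depth is unknown, so a chromosome or stretch with few peaks had few peaks detected at this threshold, which does not show that Foxk1 was absent.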

Other observations

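The tests on the threshold, on signal slopes and factors per chromosome, on the steps of q, on a common strength of neighbours, on merging and regional density together and on the share of peaks with a neighbour were chosen after their results were seen, and those on merging alone, regional density alone and windows within chromosomes after the main values were seen but before their own. The densest stretches of 100 kb lay on chromosome 19 from 5800001 to 5900000, with 20 peaks, chromosome 11 from 86400001 to 86500000, with 18, and chromosome 17 from 80100001 to 80200000, with 17. No window of this size exceeded 11 peaks in 200 shuffles within chromosomes. Median signal values in these stretches were 21.5, 23.2 and 19.9, against 17.8 for all peaks, and over the 10 fullest such windows they ranged from 16.0 on chromosome 6 to 27.9 on chromosome 19. At 1 Mb, the fullest windows were chromosome 19 from 5000001 to 6000000, with 69 peaks, and chromosome 15 from 102000001 to 103000000, with 61, against at most 42 in shuffles; their median signal values were 18.2 and 18.1.

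The longest stretch between neighbouring peaks was 12.1 Mb on X, between summits at 21332399 and 33414831. The longest autosomal ones were on chromosome 7, of 7.78 Mb between 39015645 and 46800411 and of 6.74 Mb between 6748741 and 13490766. Of 104 stretches over 2 Mb, 16 lay on X, 13 on chromosome 7 and 11 on chromosome 12, and none on chromosomes 15 and 19.

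The uneven density of chromosomes is a candidate for a closer look, because chromosomes 7 and 12 carried so few peaks. The unevenness was not confined to peaks near the threshold. The coefficient of variation across chromosomes was 1.06 times as large in peaks at or above the median signal value as in those below. This ratio cannot exclude an effect of the threshold, because a factor on all signal values of a chromosome would also change how many peaks pass it. A difference in the number of sites alone is argued against. Density ratios at a signal value of at least 50 followed those of all peaks with a slope of 1.48 on log scales (95% interval 1.31 to 1.67, and 1.41 without X). Equal signal values would give 1. The argument holds also for a lack of sequence to which reads can be assigned, as far as it changes only the number of sites. Dense stretches held more peaks with signal values of at least 50 within chromosomes too. The excess slope was 0.17 (0.09 to 0.26) over the 477 windows of 5 Mb with at least 10 peaks and 0.19 over all 510 with a peak. Between chromosomes it was 0.48 (0.31 to 0.67), or 0.44 in the same kind of Poisson model and 0.41 without X. The relation at the 5 Mb scale was thus too weak to be the whole cause. Other scales were not measured, so a relation that grows with scale is not excluded. A factor per chromosome multiplying all signal values, if their scale has a true zero, gives a slope of 1.37 between signal values of at least 20 and at least 50. The observed slope was 1.36 (1.23 to 1.52). Each factor was the one that gives the density of its chromosome at signal values of at least 20. The comparison therefore asked only whether densities at 50 follow from those at 20, and 1.37 is not an independent prediction. Peaks that reach 50 are also part of those that reach 20. For the median of peaks at or above the overall median, the factor missed the observed value beyond the 95% interval on 1 of 19 chromosomes (chromosome 17). Chromosome 19 was left out, as its factor reaches below the list. This check of medians had little power. The predicted medians ranged only from 25.04 to 28.5, and the interval of observed minus predicted on X ran from -0.48 to 3.36. X also had the largest difference, with an observed median of 26.4 against 25.04 predicted. The factors needed were graded, from 0.47 on X, 0.66 on chromosome 12 and 0.70 on chromosome 7 to 1.43 on chromosome 11 and 1.62 on chromosome 19. They take all chromosomes to have the same number of sites per Mb. Under that assumption, copy number as the only source would have to be graded in the same way. The number of sites may differ as well, so the grading does not argue for or against copy number. Copy number and gene content were not measured here and stay open, and no biological explanation was tested.

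Clustering of peaks was weighed against split summits and regional density. After merging summits closer than 2000 bp the ratio of observed to shuffled spacing was 0.51, and with shuffling within 1 Mb windows it was 0.64, both under the bound of 0.7 set beforehand for an explanation that is insufficient alone. Applying both together gave 0.73, with a median of 34.1 kb against 45.9 to 47.9 kb in 1000 shuffles (permutation p = 0.002, the smallest they can give), and this ratio did not meet the bound of 0.7. Judged instead by the range of the shuffles, a criterion chosen after the result was seen, the observed median lay below all of them. That range is narrow, and density that changes inside a 1 Mb window would also place the observed median below it. Whether the pair suffices as the whole cause was therefore not settled. Stretches of open chromatin or genes on a scale below 1 Mb were not tested.

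The q-values came in steps that may show how they were made. Among the 11201 peaks with a q-value under 0.001 and above the lowest, q multiplied by the rank of the peak fell within its rounding step (at most 0.0075) of a whole number plus 0.5 for 96.2%, where chance would give 0.92%. A candidate explanation is a count of background calls plus 0.5, divided by the number of peaks at that signal value or higher; the whole number reached 287 at the last peak. Read this way, the 2896 peaks with signal values under 12 added 128 background calls, or 4.42% of their number, whereas the 6519 peaks from 15 to 20 added 16, or 0.25%. The weakest peaks would then be less certain than the limit of 0.01 on the whole list conveys.

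A common strength of peaks in the same neighbourhood was not seen in the listed signal values. The Spearman correlation of signal values over 9396 pairs of adjacent peaks under 10000 bp apart was 0.0034 (permutation p = 0.80, two-sided, 1000 permutations), within the permuted range of -0.03 to 0.04, and it was -0.005 for the 940 pairs under 500 bp apart. Adjusted over the 13 correlations computed, no p was under 0.05. The list ends at a signal value of 11.32, so a strength shared by neighbours could show as more peaks rather than as higher values. The correlation therefore cannot exclude a shared strength. Pairs of peaks are not independent replicates. The tests prepared for a positive correlation (signal differences between regions, reads shared between summits) were not run as tests of a cause, since no such correlation was found. The 10% of peaks with the highest signal values had a neighbour within 2000 bp more often than the 10% with the lowest, in 29.99% against 22.4% (permutation p = 0.002, the smallest that 1000 permutations can give). Strong sites split into several summits, and dense stretches with more strong peaks, could give the same difference. It therefore does not show a strength shared by neighbours.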
